A study of Mus musculus with 6 samples.

How the data were processed

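RNA of sorted YFP-positive cells from primary pancreatic tumours of KPCY mice was measured in 6 libraries, 3 of EpCAM+ and 3 of EpCAM- cells. Per the labels' protocols, libraries were made with the KAPA mRNA HyperPrep kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, STAR 2.5.2, RSEM and DESeq2 1.24.0 were used with the mouse genome build GRCm38, and the notes give no role or order for these tools. The deposited values are on a log2 scale, normalised between libraries by the authors. Which transform the authors used, and with which annotation, is not given in the sources used here. Values ran from about -1.52 to 20.05 on the log2 scale, and their back-transformed sums were of like size in all libraries. Because the values are normalised, the sequencing depth of each library is unknown, and no interval or detection limit that needs it is given.

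Whole reads could not be recovered. Between 27.7% and 30.4% of the low values in a library lay within 0.1 of a whole multiple of the smallest step, where random values give 20%. The median SD over the 6 libraries was 0.0625 for genes with a mean log2 value under 0, 0.594 for means between 4 and 6 and 0.261 for means between 10 and 12. Whether the unknown transform shrinks the fold changes of tested genes with low levels was not tested.

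The test had been planned on the log2 of a normalised value plus a pseudocount of 1. As the deposited values were already on a log2 scale, they were tested as deposited with no pseudocount, and the planned scale was run as an alternative. Genes with a mean back-transformed value of at least 10 over the 6 libraries were tested, 15783 of 25978. The groups were compared with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and no covariate, and p-values, which are two-sided, were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Fold changes are EpCAM- minus EpCAM+ on the deposited log2 scale. With 3 libraries against 3, the smallest p that an exact permutation test can give is 0.1, so no single value was tested that way.

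The 46 gene lists, the rule for named genes, the tests and most alternatives were chosen before the data were examined. The rule named genes of the sort and genotype, among them Epcam and Trp53, the 10 genes that rose most and the 10 that fell most among those with a mean of at least 100 and no overlap between groups, and up to 4 members of each list with the largest change past the test. Further members are named where they did not pass, and a few were chosen after their values were seen, as stated where they first appear. Some genes that the rule takes are not reported here. The 42 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01 and again with a correlation estimated from the data, and with fry, and adjusted over all tested lists. Camera compares a list with the other genes. Fry, which asks whether the genes of a list move, on balance, one way, passed for 27 lists, against 22 for camera and 3 for camera with an estimated correlation. Lists that share genes are not independent.

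Gene symbols and coordinates were taken from the GENCODE M21 annotation of GRCm38 by Ensembl identifier, which matched 25831 identifiers and left 147 without a symbol. The listed symbols Cyr61 and Ctgf, which are older names of Ccn1 and Ccn2, and Siglech, Gzma and Slc4a1 were among those with no match. Values identical to those of another gene in all libraries occurred for 4261 genes, of which 38 were tested.

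The procedure was tested on simulated data for the comparison of EpCAM- with EpCAM+, over 15783 genes with 50 genes changed at each size. It recovered 6%, 48%, 90% and 96% of genes with a true log2 fold change of 0.5, 1, 2 and 4, and 6.98% of its calls were false. It called 4 of 4 simulated lists of 20 genes shifted by 1 log2 unit and 0 of 36 unshifted lists. The simulated genes were drawn independently of each other, so the lists give no check of camera where members are correlated. Far fewer genes were changed than the 6850 called in the data, so these shares need not hold there.

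Alternatives were pseudocounts of 0.5, 1 and 5 on back-transformed values, no filter, a filter at a mean of 50, scaling by the TMM formula or the upper quartile, quantile normalisation, the replicate number as a term, array weights, a minimum log2 fold change of 1, each library left out in turn, and EpCAM+ replicate 1 and EpCAM- replicate 3 left out together. The pseudocount of 1 and the last of these were chosen after seeing the data. Count-based tests were not run because whole reads were not recovered. The series text calls the 3 libraries of a group biological replicates, and no label says whether libraries with the same number share a tumour or were made from separate animals, so p-values measure the spread between these samples.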

Results

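RNA was sequenced from sorted cells of primary tumours of KPCY mice, a model of pancreatic cancer. In these mice, Pdx1-Cre deletes Trp53 and turns on a yellow fluorescent protein (YFP) in pancreatic cells and their descendants. Per the labels, the mice were of C57BL/6 background and between 5 and 7 weeks old, and YFP-positive cells of primary tumours were sorted by EpCAM, a surface adhesion protein of epithelial cells. The 6 libraries fall into 3 from EpCAM+ cells and 3 from EpCAM- cells, with 3 biological replicates per group. The comparison asks which genes differ between YFP-positive cells of these tumours that carry EpCAM on their surface and those that do not. As Pdx1-Cre also marks normal pancreas, not all sorted cells need be tumour cells. The deposited values are normalised log2 levels of 25978 genes, so the sequencing depth of each library is unknown. Whether libraries with the same replicate number came from the same tumour is not given in the sources used here.

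Libraries of the same group correlated more closely than libraries of different groups. Over the 15783 tested genes, the Pearson correlation between libraries lay between 0.977 and 0.989 within groups and between 0.854 and 0.883 across groups. The first principal component held 83.8% of the variance and separated the groups. The next held 7.28% and set both replicate 1 libraries, at -27.2 (EpCAM+) and -45.4 (EpCAM-), apart from the other 4, which lay between 12.3 and 24.6. EpCAM- replicate 1 also had the lowest array weight, 0.369, and without it 7300 genes passed in place of the 6850 given below. Mitochondrially encoded genes took 2.31%, 2.63% and 2.86% of the back-transformed total in the EpCAM+ libraries and 1.16%, 1.61% and 1.60% in the EpCAM- libraries. The most abundant gene was Clu, a secreted chaperone, in each EpCAM+ library and Fn1, the matrix protein fibronectin, in each EpCAM- library.

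EpCAM- libraries had low levels of junction, keratin and other epithelial genes and high levels of the mesenchymal regulators Prrx1, Snai2 and Twist1 and of vimentin. Genes of gastric-type and acinar differentiation were likewise low in EpCAM- libraries. At a Benjamini-Hochberg adjusted p under 0.05 in limma, 6850 of the 15783 tested genes differed, of which 3197 were higher and 3653 lower in EpCAM- cells. A log2 fold change of at least 1 was reached by 1478 of the higher and 2289 of the lower genes. The decrease was at least 16-fold for 424 genes and the increase for 102. The values of the groups did not overlap for 6808 of the changed genes and for 56.3% of all tested genes, where chance gives 10%. Without EpCAM+ replicate 1 and EpCAM- replicate 3, in which fibroblast markers stood apart from the rest of their group, 4369 genes passed, an alternative chosen after seeing the data. Cdh1, Foxc2, Col14a1, Thbs1, Fer1l6, Ereg, Cst6, Sox9, Aqp1 and Pax6 fall outside the rule for named genes and were chosen after their values were seen.

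Epcam itself (ENSMUSG00000045394, GRCm38 chromosome 17, 87635979 to 87651129), whose protein was used for the sort, checks the labels. Its log2 level was 14.95 ± 0.096 (SD, n = 3) in EpCAM+ and 7.96 ± 0.64 (SD, n = 3) in EpCAM- libraries, a log2 fold change of -7.00 ± 0.30 (SE) with a limma adjusted p of 7.43e-06. Trp53, the gene deleted in these mice (chromosome 11, 69580359 to 69591873), had a log2 level of 7.15 ± 0.21 in EpCAM+ and 7.38 ± 0.088 in EpCAM- libraries (SD, n = 3 per group), so RNA counted for it was present in every library. Which exons that RNA covers cannot be read from values per gene. Its log2 fold change of 0.23 ± 0.17 (SE) did not pass (adjusted p = 0.331). After quantile normalisation its adjusted p was 0.0295, the only alternative under which it passed, and over all alternatives that p lay between 0.0295 and 0.672.

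The 10 genes that rose most among well expressed genes without overlap included secreted, guidance and matrix genes. Serpinb2, an inhibitor of plasminogen activators (chromosome 1, 107511423 to 107535478), rose from 4.40 ± 0.26 to 11.05 ± 0.67 (SD, n = 3 per group), a log2 fold change of 6.65 ± 0.34 (SE, adjusted p = 1.51e-05). The axon guidance ligand Sema3a rose from 5.13 ± 0.48 to 10.98 ± 0.097 (SD, n = 3 per group), by 5.86 ± 0.25 (SE, adjusted p = 7.43e-06). The growth cone protein gene Gap43 rose by 5.88, the urea transporter gene Slc14a1 by 6.06 and the tetraspanin gene Tspan11 by 5.90. The collagen receptor Ddr2 (5.82), the collagens Col3a1 (5.61) and Col15a1 (5.56), the gelatinase Mmp2 (5.55) and Prrx1 (6.57) complete that set. The 10 genes that fell most were all genes of the exocrine pancreas, namely Amy2a2, Amy2a3, Amy2a4, Pnliprp1, Ctrb1, Prss2, Cel, Cpb1, Reg2 and Cpa1. Their log2 fold changes lay between -8.54 for Amy2a3 and -7.40 for Cpa1. Amy2a2, Amy2a3 and Amy2a4 are near-identical amylase copies whose deposited values were the same in all 6 libraries, so their individual levels are uncertain.

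**Figure D1:**
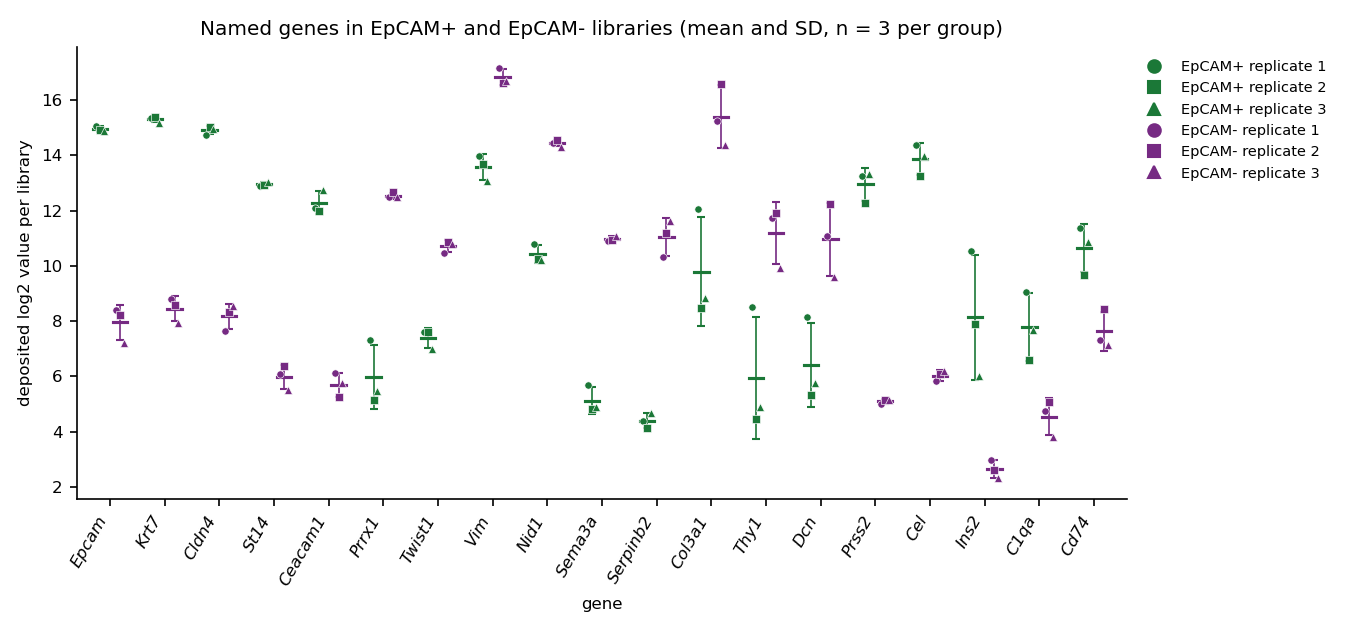
Deposited log2 values of 19 named genes in each of the 6 libraries, with EpCAM+ in green, EpCAM- in purple, symbols for the replicates, and bars for the mean and SD of 3 libraries. Epcam, Krt7 and St14 lie higher in every EpCAM+ library, Prrx1, Vim and Sema3a lie higher in every EpCAM- library, and Col3a1, Thy1 and Dcn lie higher in EpCAM+ replicate 1 than in the other EpCAM+ libraries.

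Epithelial genes fell as a group. For cell-cell junctions and polarity, of 25 tested members, 0 rose, 24 fell and 1 did not pass (adjusted over the list alone, 0 rose and 25 fell). The tight junction claudins Cldn3 (-6.82 ± 0.30, SE) and Cldn4 (-6.73 ± 0.22, SE) and the polarity gene Crb3 (-6.53 ± 0.35, SE) fell by 6 log2 units or more. E-cadherin (Cdh1) fell by 3.77 on the log2 scale with an SD of 1.40 among the EpCAM- libraries. For epithelial regulators and surface proteases, of 19 tested members, 0 rose, 19 fell and 0 did not pass (adjusted over the list alone, 0 rose and 19 fell). Examples are the membrane protease St14 (-6.98 ± 0.21, SE), the splicing regulator Esrp1 (-6.53 ± 0.23, SE) and the trafficking GTPase Rab25 (-6.38 ± 0.30, SE). For keratins, of 12 tested members, 0 rose, 12 fell and 0 did not pass (adjusted over the list alone, 0 rose and 12 fell), with Krt7 at -6.85 ± 0.22 (SE) and Krt17 at -6.68 ± 0.23 (SE). In camera, the junction (adjusted p = 3.88e-15), regulator (adjusted p = 9.58e-14) and keratin (adjusted p = 4.85e-08) lists passed, and these 3 were the lists that also passed with an estimated correlation, at adjusted p of 0.05, 0.0456 and 0.05, the first and last being just under the threshold before rounding. The sort on EpCAM, itself an epithelial gene, selects in the direction of these lists.

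Mesenchymal regulators rose in EpCAM- cells. For the transcription factors of epithelial-mesenchymal transition (EMT), of 12 tested members, 7 rose, 2 fell and 3 did not pass (adjusted over the list alone, 7 rose and 2 fell). Prrx1 (chromosome 1, 163245119 to 163313710) rose from 5.98 ± 1.16 to 12.54 ± 0.11 (SD, n = 3 per group), by 6.57 ± 0.52 (SE, adjusted p = 9.12e-05). Snai2 rose by 3.54 ± 0.28 (SE) and Twist1 by 3.32 ± 0.21 (SE). Snai3, a Snail family member, went the other way at -3.52 ± 0.22 (SE). Foxc2, the other member that fell, had -1.52 at an adjusted p of 0.0497, and 1 factor fell when any library but EpCAM- replicate 1 was left out. For mesenchymal cytoskeleton and adhesion genes, of 15 tested members, 8 rose, 0 fell and 7 did not pass (adjusted over the list alone, 8 rose and 0 fell). The intermediate filament gene Vim rose from 13.58 ± 0.47 to 16.83 ± 0.30 (SD, n = 3 per group), and S100a4 (4.39 ± 0.40, SE), the cadherin Cdh11 (4.35 ± 0.68, SE) and N-cadherin, Cdh2 (2.06 ± 0.24, SE), rose with it. Acta2 (1.69, adjusted p = 0.249) and Cd44 (0.043, adjusted p = 0.860) did not pass. Camera called the EMT factors (adjusted p = 0.0105, and adjusted p = 0.493 with an estimated correlation) and the mesenchymal genes (adjusted p = 0.00113, and adjusted p = 0.493 with an estimated correlation). The mean log2 level of the mesenchymal list was 11.29, 11.02 and 10.23 in EpCAM- replicates 1, 2 and 3 and 9.65, 8.94 and 9.04 in EpCAM+ replicates 1, 2 and 3. It was lowest of EpCAM- in replicate 3 and highest of EpCAM+ in replicate 1, as were the fibroblast markers given below. Prrx1 stood at 7.31, 5.15 and 5.48 in EpCAM+ replicates 1, 2 and 3.

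Collagens and matrix glycoproteins were higher in EpCAM- libraries, with larger differences between libraries of a group. For collagens, of 19 tested members, 15 rose, 1 fell and 3 did not pass (adjusted over the list alone, 16 rose and 1 fell). Col3a1 rose by 5.61 ± 0.99 (SE), Col15a1 by 5.56 ± 0.60 (SE) and Col5a1 by 5.19 ± 0.64 (SE), and Col14a1, the only member that fell, had -2.03. No collagen fell without EpCAM+ replicate 1, 2 or 3 or without EpCAM- replicate 2. Col1a1 rose by 4.27 ± 1.03 (SE, adjusted p = 0.0142) and lost its call without EpCAM+ replicate 3, at an adjusted p of 0.0574, within a range between 0.000135 and 0.0574 over all alternatives. For matrix glycoproteins and crosslinkers, of 26 tested members, 20 rose, 1 fell and 5 did not pass (adjusted over the list alone, 20 rose and 1 fell). Thrombospondin 2, Thbs2 (5.43 ± 0.68, SE), decorin, Dcn (4.56 ± 0.88, SE), and the basement membrane linker Nid1 (4.02 ± 0.17, SE) rose. Thbs1, the only member that fell, had -0.89, and none fell without EpCAM+ replicate 3. Fn1, at 18.56 ± 0.18 and 19.48 ± 0.50 (SD, n = 3 per group), did not pass (adjusted p = 0.196). Camera called the collagens (adjusted p = 1.02e-05, and adjusted p = 0.431 with an estimated correlation) and the glycoproteins (adjusted p = 1.13e-07, and adjusted p = 0.431 with an estimated correlation). Fibroblast markers moved with these genes. Their mean log2 level was 10.32, 10.29 and 8.53 in EpCAM- replicates 1, 2 and 3. It was 7.87, 5.92 and 6.16 in EpCAM+ replicates 1, 2 and 3. The fibroblast list shares Col1a1, Col3a1 and Col14a1 with the collagens and Dcn, Lum, Fbln1, Fbln2 and Mfap5 with the glycoproteins. A part of this likeness was therefore fixed by the lists.

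Laminins, matrix proteases and integrins changed in both directions. For basement membrane laminins, of 10 tested members, 4 rose, 3 fell and 3 did not pass (adjusted over the list alone, 4 rose and 3 fell). The epithelial chains Lama3 (-6.60 ± 0.27, SE) and Lamb3 (-2.72 ± 0.52, SE) fell. The list's median was 0.51, its mean -0.20, and camera, with an upward direction, did not pass (adjusted p = 0.793). That median was 0.31 without EpCAM- replicate 1, 0.32 without EpCAM- replicate 3 and 0.26 without EpCAM+ replicate 1 as well. After quantile normalisation the laminin direction was downward (adjusted p = 0.871, between 0.686 and 0.899 over all alternatives). For matrix proteases and inhibitors, of 26 tested members, 12 rose, 5 fell and 9 did not pass (adjusted over the list alone, 12 rose and 6 fell), with Mmp2 at 5.55 ± 0.91 (SE) and the epithelial genes Mmp7 (-6.74 ± 0.36, SE), Serpinb5 (-5.45 ± 0.21, SE) and Mmp15 (-4.51 ± 0.31, SE) among those that fell. For integrins, of 18 tested members, 7 rose, 3 fell and 8 did not pass (adjusted over the list alone, 7 rose and 3 fell), with Itgb6 at -4.47 ± 0.18 (SE), Itga1 at -2.18 ± 0.29 (SE), Itgb7 at 3.24 ± 0.42 (SE) and Itga11 at 1.89 ± 0.34 (SE). Neither proteases (adjusted p = 0.164) nor integrins (adjusted p = 0.348) passed camera. The proteases passed without EpCAM+ replicate 1 and EpCAM- replicate 3 (adjusted p = 0.0198, between 0.0198 and 0.728 over all alternatives).

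Differentiation genes of the pancreas and the gastric lineage fell. For markers of the classical subtype of pancreatic cancer and of gastric-type mucosa, of 27 tested members, 1 rose, 26 fell and 0 did not pass (adjusted over the list alone, 1 rose and 26 fell). The adhesion molecule Ceacam1 (-6.58 ± 0.28, SE), the gastrokine Gkn3 (-6.42 ± 0.29, SE), Dmbt1 (-6.34 ± 0.36, SE) and the secretory gene Agr2 (-6.31 ± 0.34, SE) fell by more than 6 log2 units, and Fer1l6, the only member that rose, had 1.25. No member rose without EpCAM+ replicate 1 or 3 or without EpCAM- replicate 1 or 3. For basal-like markers, of 17 tested members, 2 rose, 10 fell and 5 did not pass (adjusted over the list alone, 2 rose and 10 fell), with Krt17 at -6.68 ± 0.23 (SE), Ly6d at -5.73 ± 0.59 (SE) and Tns4 at -5.66 ± 0.29 (SE). The epidermal growth factor receptor ligand gene Ereg (2.35) and the cystatin gene Cst6 (3.40) were the basal-like members that rose. For pancreatic and foregut transcription factors, of 19 tested members, 2 rose, 14 fell and 3 did not pass (adjusted over the list alone, 2 rose and 14 fell). Onecut3 (-5.77 ± 0.28, SE), Nr5a2 (-5.50 ± 0.35, SE) and Hnf4a (-4.94 ± 0.24, SE) fell, the rising members were Klf4 (0.82) and Sox9 (0.70), and Pdx1 (-0.13, adjusted p = 0.605), Gata4 (0.18) and Nkx6-1 (0.11) did not pass. The number of rising factors was 0 without EpCAM+ replicate 3 or EpCAM- replicate 2, and 1 without EpCAM+ replicate 1 or 2 or EpCAM- replicate 3. Camera called the classical (adjusted p = 9.58e-14, and adjusted p = 0.228 with an estimated correlation), basal-like (adjusted p = 0.00170, and adjusted p = 0.409 with an estimated correlation) and transcription factor lists (adjusted p = 3.51e-05, and adjusted p = 0.120 with an estimated correlation).

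Markers of normal pancreatic cells were almost all higher in EpCAM+ libraries. For acinar cells, the enzyme-secreting cells of the pancreas, of 24 tested members, 0 rose, 22 fell and 2 did not pass (adjusted over the list alone, 0 rose and 22 fell). Pnliprp1 was at 13.98 ± 0.55 in EpCAM+ and 5.99 ± 0.015 in EpCAM- libraries (SD, n = 3 per group), Ctrb1 fell by 7.85 ± 0.28 (SE), Prss2 by 7.84 ± 0.28 (SE) and Cel by 7.83 ± 0.28 (SE). An SD as small as that of Pnliprp1 in EpCAM- could mark a floor of the unknown transform. This was not tested, so the size of its fold change is uncertain. The acinar list took 0.583%, 0.291% and 0.575% of the back-transformed total in EpCAM+ replicates 1, 2 and 3 and at most 0.00432% in an EpCAM- library. For duct cells, of 14 tested members, 2 rose, 11 fell and 1 did not pass (adjusted over the list alone, 2 rose and 12 fell), with Krt7 (-6.85 ± 0.22, SE), the carbonic anhydrase Car2 (-6.35 ± 0.42, SE) and the mucin Muc1 (-5.83 ± 0.24, SE) falling. The duct members that rose were Aqp1 (2.51) and Sox9 (0.70), and 1 duct member rose when EpCAM+ replicate 1 or 3 or EpCAM- replicate 2 or 3 was left out. For islet endocrine cells, of 15 tested members, 1 rose, 14 fell and 0 did not pass (adjusted over the list alone, 1 rose and 14 fell). The hormone gene Pyy fell by 5.47 ± 0.34 (SE), and Ins2 stood at 10.52, 7.90 and 6.01 in EpCAM+ replicates 1, 2 and 3. Pax6, an islet and neural transcription factor and the only member that rose, had 2.74. Camera called acinar (adjusted p = 9.58e-14, and adjusted p = 0.388 with an estimated correlation), duct (adjusted p = 1.18e-05, and adjusted p = 0.120 with an estimated correlation) and islet genes (adjusted p = 3.51e-05, and adjusted p = 0.534 with an estimated correlation).

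Receptor and signalling genes changed member by member. For receptor tyrosine kinases, of 29 tested members, 7 rose, 15 fell and 7 did not pass (adjusted over the list alone, 8 rose and 16 fell). Ddr2 (5.82 ± 0.51, SE) and Pdgfrb (4.13 ± 0.83, SE) rose, and Fgfr4 (-5.60 ± 0.21, SE), Erbb3 (-5.28 ± 0.26, SE) and Mst1r (-4.55 ± 0.29, SE) fell. Camera called this list downwards (adjusted p = 0.0388, and adjusted p = 0.388 with an estimated correlation), and it missed the threshold without EpCAM+ replicate 1 (adjusted p = 0.0595), without EpCAM+ replicate 2 (adjusted p = 0.0512) and without EpCAM+ replicate 1 and EpCAM- replicate 3 together (adjusted p = 0.0800). Over all alternatives its adjusted p lay between 0.00453 and 0.388. For the TGF-beta pathway, of 25 tested members, 10 rose, 3 fell and 12 did not pass (adjusted over the list alone, 11 rose and 5 fell). The matrix protein gene Tgfbi (4.59 ± 0.60, SE), the co-receptor Tgfbr3 (4.22 ± 0.35, SE), the activin subunit Inhba (2.15 ± 0.30, SE) and Ltbp1 (1.97 ± 0.12, SE) rose. Its camera adjusted p was 0.0650, which became 0.0310 without EpCAM- replicate 1, 0.0358 without EpCAM- replicate 3, 0.0259 without EpCAM+ replicate 1 as well and 0.0343 with no filter on low values (between 0.0259 and 0.607 over all alternatives), and 1 in place of 3 members fell without EpCAM+ replicate 1. For genes of MAPK output, of 17 tested members, 9 rose, 2 fell and 6 did not pass (adjusted over the list alone, 11 rose and 2 fell). Etv1 rose by 2.35 ± 0.16 (SE) and Spred1 by 1.15 ± 0.18 (SE), and Phlda1 stood at -1.45 ± 0.16 (SE). Camera called MAPK output upwards (adjusted p = 0.0153, and adjusted p = 0.493 with an estimated correlation), with an adjusted p of 0.102 after quantile normalisation and between 0.00511 and 0.493 over all alternatives. Without EpCAM+ replicate 3, 4 in place of 9 members rose, and 1 in place of 2 fell without EpCAM+ replicate 2 or 3.

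Ligands and receptors of developmental pathways were also divided. For the Wnt pathway, of 28 tested members, 7 rose, 10 fell and 11 did not pass (adjusted over the list alone, 8 rose and 10 fell). The ligand Wnt7a (-5.63 ± 0.41, SE) and the receptor ligase Rnf43 (-5.25 ± 0.25, SE) fell, and the secreted Wnt modulators Dkk2 (3.68 ± 0.30, SE) and Dkk3 (2.91 ± 0.26, SE) rose. The Wnt members that fell numbered 6 without EpCAM+ replicate 1 and 6 without EpCAM+ replicate 2, those that rose numbered 4 without EpCAM+ replicate 3, and camera, with a downward direction, did not pass (adjusted p = 0.816). Without EpCAM+ replicate 1 the Wnt direction was upward (adjusted p = 0.977, between 0.488 and 0.977 over all alternatives). For the Notch pathway, of 15 tested members, 2 rose, 6 fell and 7 did not pass (adjusted over the list alone, 2 rose and 6 fell), with the ligands Jag2 (-4.36 ± 0.21, SE) and Dll1 (-3.01 ± 0.29, SE) falling and Rbpj at 1.57 ± 0.16 (SE). The Notch members that fell numbered 3 without EpCAM+ replicate 1, those that rose numbered 4 without EpCAM- replicate 1, and camera did not pass (adjusted p = 0.447). For the Hedgehog pathway, of 11 tested members, 5 rose, 4 fell and 2 did not pass (adjusted over the list alone, 5 rose and 4 fell). The ligand Ihh fell by 3.41 ± 0.24 (SE), and the transcription factor Gli3 (3.71 ± 0.16, SE) and the ligand-binding Hhip (2.86 ± 0.54, SE) rose. Of the Hedgehog members 3 rose without EpCAM- replicate 1, EpCAM+ replicate 2 or EpCAM+ replicate 3, 2 fell without EpCAM+ replicates 2 or 3 or EpCAM- replicates 2 or 3, and camera did not pass (adjusted p = 0.547). For YAP and TEAD targets, of 18 tested members, 5 rose, 8 fell and 5 did not pass (adjusted over the list alone, 5 rose and 8 fell), with Axl at 2.79 ± 0.21 (SE), F3 at -2.62 ± 0.26 (SE), Wwc1 at -2.25 ± 0.14 (SE) and a camera adjusted p of 0.547. For stem cell markers of pancreatic cancer, of 14 tested members, 3 rose, 7 fell and 4 did not pass (adjusted over the list alone, 3 rose and 7 fell), with Prom1 at -6.51 ± 0.30 (SE), Cd24a at -3.26 ± 0.30 (SE) and a camera adjusted p of 0.218.

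**Figure D2:**
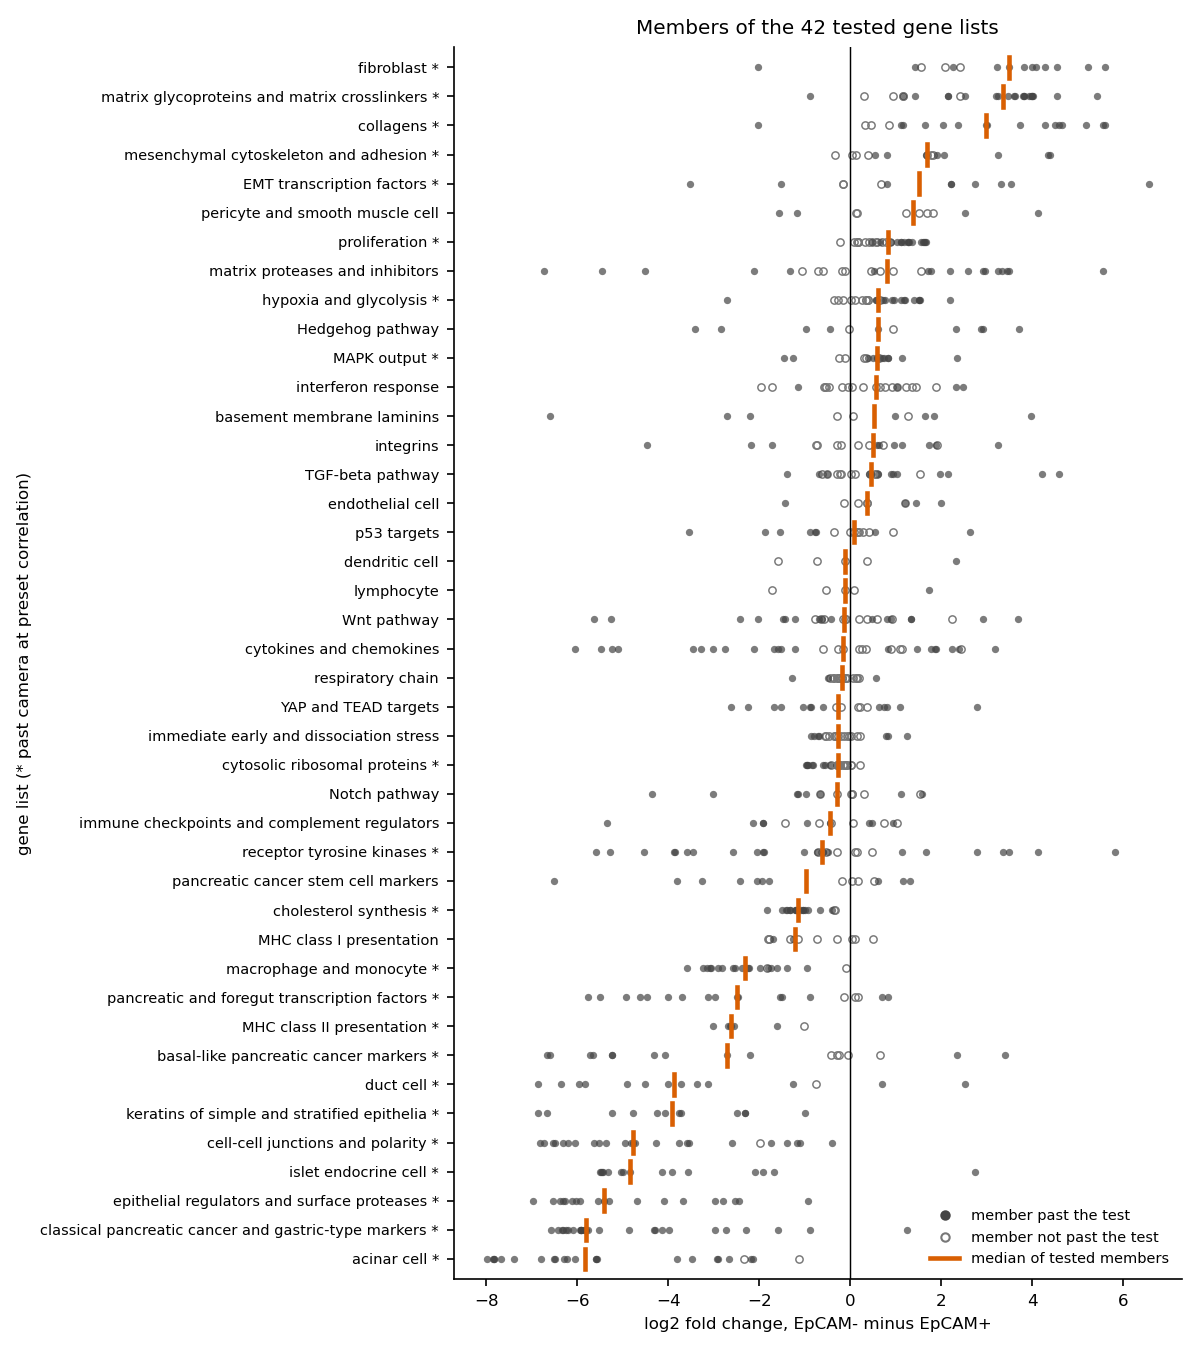
Log2 fold change of each tested member of the 42 tested gene lists (horizontal axis, EpCAM- minus EpCAM+), with filled points past the limma test, open points not past it, orange bars for the list medians and asterisks for the lists past camera at its preset correlation. The medians run from -5.83 for acinar genes to 3.48 for fibroblast genes, and several signalling lists have members far from 0 on both sides.

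Proliferation genes and genes of hypoxia and glycolysis were higher, and cholesterol synthesis genes lower, in EpCAM- cells. For proliferation, of 30 tested members, 16 rose, 0 fell and 14 did not pass (adjusted over the list alone, 19 rose and 0 fell). The nucleotide reductase subunit Rrm2 (1.67 ± 0.23, SE), the mitotic kinesin Kif20a (1.65 ± 0.27, SE) and the cell cycle factor E2f1 (1.60 ± 0.18, SE) rose, and Mki67 (0.085, adjusted p = 0.701) did not pass. For hypoxia and glycolysis, of 26 tested members, 14 rose, 1 fell and 11 did not pass (adjusted over the list alone, 14 rose and 1 fell). The collagen prolyl hydroxylase P4ha1 (2.2 ± 0.32, SE) and Bnip3 (1.54 ± 0.30, SE) rose and the carbonic anhydrase Car9 went the other way at -2.70 ± 0.18 (SE). For cholesterol synthesis, of 18 tested members, 0 rose, 16 fell and 2 did not pass (adjusted over the list alone, 0 rose and 16 fell), with the sterol enzymes Idi1 (-1.5 ± 0.20, SE) and Cyp51 (-1.42 ± 0.16, SE) falling. In hypoxia and glycolysis, 8 in place of 14 members rose without EpCAM+ replicate 1 and EpCAM- replicate 3. Camera called proliferation (adjusted p = 1.04e-05, and adjusted p = 0.579 with an estimated correlation), hypoxia and glycolysis (adjusted p = 0.00131, and adjusted p = 0.579 with an estimated correlation) and cholesterol synthesis (adjusted p = 3.80e-06, and adjusted p = 0.416 with an estimated correlation). The rising proliferation genes stood higher in EpCAM+ replicate 1 than in the mean of EpCAM+ replicates 2 and 3, by a median of 0.59 log2 units. The mean log2 level of the proliferation list was 10.50 in EpCAM- replicate 1 against 9.76 and 9.92 in EpCAM- replicates 2 and 3, and without EpCAM- replicate 1 the list's median log2 fold change was 0.50 in place of 0.83.

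Ribosomal, respiratory chain and p53 target genes were tested as lists in the same way. For cytosolic ribosomal proteins, of 24 tested members, 0 rose, 9 fell and 15 did not pass (adjusted over the list alone, 0 rose and 8 fell), with Rps3 at -0.96 ± 0.21 (SE). Camera called them downwards (adjusted p = 0.0231, and adjusted p = 0.762 with an estimated correlation), but not without EpCAM- replicate 2 (adjusted p = 0.108) or EpCAM- replicate 3 (adjusted p = 0.0726), nor without EpCAM+ replicate 1 and EpCAM- replicate 3 together (adjusted p = 0.0749), and over all alternatives its adjusted p lay between 9.95e-05 and 0.762. The ribosomal genes that fell numbered 5 without EpCAM+ replicate 1, 4 without EpCAM+ replicate 2, 3 without EpCAM+ replicate 3, 4 without EpCAM- replicate 2 or 3, and 0 without EpCAM+ replicate 1 and EpCAM- replicate 3 together. For the respiratory chain, of 22 tested members, 1 rose, 2 fell and 19 did not pass (adjusted over the list alone, 0 rose and 2 fell). Uqcrc2 stood at -1.28 ± 0.21 (SE), and camera did not pass (adjusted p = 0.382), whereas without EpCAM- replicate 1 the adjusted p was 0.0252 and 11 members fell. Over all alternatives that p lay between 0.0252 and 0.859, 1 member fell without EpCAM+ replicate 3, and none rose without EpCAM+ replicate 1, 2 or 3. For p53 targets, of 17 tested members, 2 rose, 6 fell and 9 did not pass (adjusted over the list alone, 2 rose and 6 fell). The desmosomal gene Perp (-3.55 ± 0.22, SE) and Pmaip1 (-1.88 ± 0.21, SE) fell, Eda2r rose by 2.62 ± 0.37 (SE), and Cdkn1a (0.28, adjusted p = 0.390) did not pass. The p53 list had a median of 0.09, a mean of -0.26 and, with a downward direction, a camera adjusted p of 0.664, and the members that rose numbered 4 without EpCAM- replicate 1 and 1 without EpCAM+ replicate 3. Its median was -0.0058 without EpCAM+ replicate 1, 0.14 and -0.20 without EpCAM- replicate 1 or 2, and 0.044 without EpCAM+ replicate 1 and EpCAM- replicate 3, where 1 rose and 3 fell.

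Among immune genes, MHC class II genes were lower in EpCAM- libraries. For MHC class II presentation, of 7 tested members, 0 rose, 6 fell and 1 did not pass (adjusted over the list alone, 0 rose and 7 fell), with the invariant chain Cd74 at -3.01 ± 0.50 (SE), H2-Aa at -2.68 ± 0.57 (SE) and H2-Ab1 at -2.63 ± 0.50 (SE). Camera called this list (adjusted p = 0.00659, and adjusted p = 0.579 with an estimated correlation). Macrophage markers moved with it, as the mean log2 level in EpCAM+ replicates 1, 2 and 3 was 8.39, 6.79 and 7.90 for class II and 8.21, 6.27 and 6.96 for macrophage genes. For MHC class I presentation, of 12 tested members, 0 rose, 2 fell and 10 did not pass (adjusted over the list alone, 0 rose and 0 fell), and camera did not pass (adjusted p = 0.199). The class I genes that fell, H2-K1 (-1.71) and H2-D1 (-1.27), lost their calls when EpCAM- replicate 1 or 3 or EpCAM+ replicate 2 or 3 was left out. Without EpCAM+ replicate 1 a single class I gene fell, without EpCAM+ replicate 3 a single class I gene rose, and without EpCAM- replicate 2 camera gave an adjusted p of 0.0294 and 7 class I members fell. Over all alternatives the class I adjusted p lay between 0.0294 and 0.812. For the interferon response, of 23 tested members, 3 rose, 1 fell and 19 did not pass (adjusted over the list alone, 1 rose and 0 fell), with Ifit2 at 2.49 ± 0.27 (SE). Camera gave this list an adjusted p of 0.368, or 0.0252 with 9 members rising without EpCAM- replicate 1, and between 0.0252 and 0.990 over all alternatives. The interferon direction was upward, and downward without EpCAM- replicate 2 (adjusted p = 0.990). In the interferon list 1 member rose without EpCAM+ replicate 1, 3 fell without EpCAM- replicate 2, and none fell without EpCAM- replicate 1 or EpCAM+ replicate 1, 2 or 3. For cytokines and chemokines, of 31 tested members, 8 rose, 13 fell and 10 did not pass (adjusted over the list alone, 10 rose and 13 fell). Il1a (-6.05 ± 0.38, SE), Il23a (-5.47 ± 0.21, SE), Il1rn (-5.24 ± 0.24, SE) and Tnf (-5.11 ± 0.49, SE) fell, and camera did not pass (adjusted p = 0.547). For immune checkpoints and complement regulators, of 15 tested members, 3 rose, 6 fell and 6 did not pass (adjusted over the list alone, 3 rose and 7 fell), with the checkpoint ligand Vtcn1 at -5.34 ± 0.20 (SE), Cd274 at 0.74 (adjusted p = 0.209) and a camera adjusted p of 0.326. For immediate early and dissociation stress genes, of 21 tested members, 3 rose, 4 fell and 14 did not pass (adjusted over the list alone, 3 rose and 3 fell), with Klf2 at 1.25 ± 0.21 (SE) and a camera adjusted p of 0.545. The stress genes that fell numbered 0 without EpCAM+ replicate 2 or 3 and 1 without EpCAM+ replicate 1 or EpCAM- replicate 3, and 1 rose without EpCAM+ replicate 3.

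Markers of cells that the YFP gate should exclude were measured in the same way. For macrophages and monocytes, of 20 tested members, 0 rose, 18 fell and 2 did not pass (adjusted over the list alone, 0 rose and 19 fell). The complement gene C1qa stood at 9.06, 6.60 and 7.67 in EpCAM+ replicates 1, 2 and 3 and at 4.76, 5.08 and 3.81 in EpCAM- replicates 1, 2 and 3. Cd14 fell by 3.58 ± 0.17 (SE) and Laptm5 by 3.09 ± 0.55 (SE). Camera called macrophage genes (adjusted p = 3.51e-05, and adjusted p = 0.579 with an estimated correlation), and 11 in place of 18 fell without EpCAM- replicate 3, or 10 without EpCAM+ replicate 1 as well. For fibroblasts, of 15 tested members, 11 rose, 1 fell and 3 did not pass (adjusted over the list alone, 12 rose and 1 fell). Thy1 rose by 5.24 ± 1.09 (SE), Col3a1 by 5.61 ± 0.99 (SE) and Dcn by 4.56 ± 0.88 (SE), camera called the list (adjusted p = 0.000321, and adjusted p = 0.545 with an estimated correlation), and 7 in place of 11 rose without EpCAM+ replicate 3. The fibroblast member that fell was Col14a1, and none fell without EpCAM+ replicate 1, 2 or 3 or without EpCAM- replicate 2. For pericytes and smooth muscle, of 10 tested members, 2 rose, 2 fell and 6 did not pass (adjusted over the list alone, 2 rose and 2 fell), with Pdgfrb at 4.13 ± 0.83 (SE), Cspg4 at 2.53 ± 0.34 (SE) and a camera adjusted p of 0.306. The pericyte genes that fell, Notch3 (-1.18) and Rgs5 (-1.56), numbered 0 without EpCAM+ replicate 3 and 1 without any other single library, and 4 rose without EpCAM- replicate 3. The pericyte list passed camera without EpCAM+ replicate 1 and EpCAM- replicate 3 (adjusted p = 0.0291, between 0.0291 and 0.746 over all alternatives).

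Markers of the remaining cell types were mostly untested or did not pass. For endothelial cells, of 9 tested members, 3 rose, 1 fell and 5 did not pass (adjusted over the list alone, 3 rose and 1 fell), with Flt1 at 2.00 ± 0.36 (SE), a camera adjusted p of 0.218, and 1 rising member without EpCAM+ replicate 1 or 3. For dendritic cells, of 5 tested members, 1 rose, 0 fell and 4 did not pass (adjusted over the list alone, 1 rose and 0 fell), with Flt3 at 2.31 ± 0.38 (SE), a median of -0.11, a mean of 0.056 and, with an upward direction, a camera adjusted p of 0.918. The dendritic median was 0.32, -0.41 and -0.24 without EpCAM+ replicate 1, 2 or 3, -0.17, 0.17 and -0.33 without EpCAM- replicate 1, 2 or 3, and 0.10 without EpCAM+ replicate 1 and EpCAM- replicate 3. Without EpCAM+ replicate 2, 2 dendritic cell members and 1 lymphocyte member fell and the direction of both lists was downward, at adjusted p of 0.742 (between 0.742 and 0.957 over all alternatives) and 0.790 (between 0.603 and 0.997). For lymphocytes, of 5 tested members, 1 rose, 0 fell and 4 did not pass (adjusted over the list alone, 1 rose and 0 fell), with Trbc2 at 1.74 ± 0.26 (SE). The lymphocyte median was -0.12, the mean -0.11, and camera, with an upward direction, gave an adjusted p of 0.904. That median was 0.067 and -0.25 without EpCAM+ replicate 1 or 2, 0.16, -0.30 and -0.23 without EpCAM- replicate 1, 2 or 3, and -0.048 without EpCAM+ replicate 1 and EpCAM- replicate 3. For Schwann cells, of 4 tested members, 1 rose, 2 fell and 1 did not pass (adjusted over the list alone, 1 rose and 2 fell), with Mbp at -2.28 ± 0.28 (SE) and Ngfr at 1.22 ± 0.25 (SE), and 1 in place of 2 fell without EpCAM+ replicate 2 or 3. Of the neutrophil markers only Il1r2 was tested, with -1.10 at an adjusted p of 0.0200, and it did not pass without EpCAM+ replicate 1 or 3 or EpCAM- replicate 2 or 3, nor after quantile normalisation (adjusted p between 0.00976 and 0.114 over all alternatives). For mesothelial cells, of 3 tested members, 0 rose, 0 fell and 3 did not pass (adjusted over the list alone, 0 rose and 0 fell), while 2 rose without EpCAM+ replicate 2 and 1 fell without EpCAM- replicate 1. No erythroid marker was expressed highly enough to be tested.

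**Figure D3:**
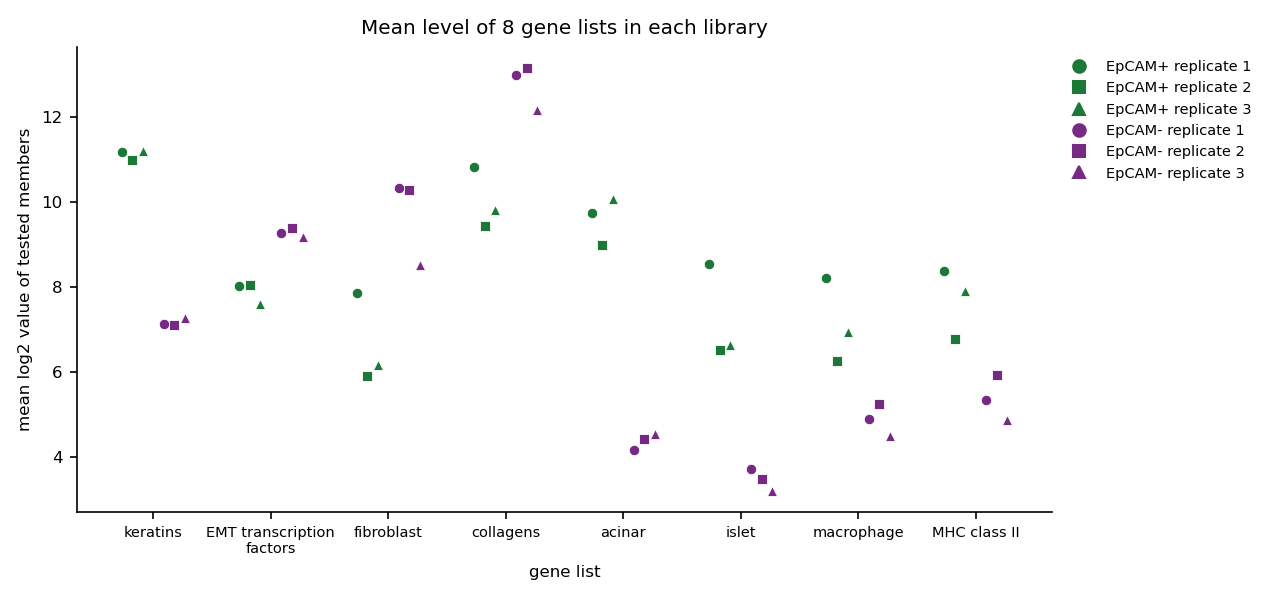
Mean log2 value of the tested members of 8 gene lists in each library, with EpCAM+ in green, EpCAM- in purple and symbols for the replicates. Keratin and EMT factor means of a group lie close together, whereas the fibroblast mean is 7.87 in EpCAM+ replicate 1 and 8.53 in EpCAM- replicate 3, and the macrophage mean is 8.21 in EpCAM+ replicate 1.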

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

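Apart from the pseudocount of 1, the pair of libraries left out together and the other splits, which were chosen after seeing the data, the alternatives below were chosen before the data were examined. Changed genes numbered between 5937 with a filter at a mean of 50 and 8006 with array weights, against 6850. That filter left 12677 genes to test in place of 15783, and 11 of the main calls among them were lost. With a log2 fold change of at least 1, 3767 genes passed (1478 higher, 2289 lower), since fewer genes meet that minimum. With libraries left out, changed genes numbered between 4369 and 7300, higher ones between 1907 and 3325 and lower ones between 2462 and 3975. Of the 6850 genes, 4670 kept their call without any single library, between 575 and 1899 lost it in a given leave-out, and 0 reversed. The count of 4369 came from a fit with fewer samples. No other pair of libraries was left out, so the cause of the drop was not tested. Quantile normalisation moved the median of all genes by 0.13 on the log2 scale and gave 4241 higher and 3246 lower genes, a share of 56.6% higher against 46.7%. Camera with an estimated correlation called 3 lists against 22, the preset correlation being replaced by one estimated for each list.

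Apart from the minimum fold change, which was not run on them, no alternative changed the direction of a named gene, and at most 21 of the 171 lost their call under 1 alternative. Lists that changed direction never passed the test in that direction, and the cause was not tested. They were lymphocyte genes with no filter (adjusted p = 0.603), laminins after quantile normalisation (adjusted p = 0.871) and, with libraries left out, the following. Their ranges of adjusted p are over all such fits, in either direction. The Wnt list lay between 0.656 and 0.977, dendritic cells between 0.742 and 0.917, lymphocytes between 0.701 and 0.997 and the interferon response between 0.0252 and 0.990. The interferon value of 0.0252, without EpCAM- replicate 1, was upward as in the main fit. Its downward fit, without EpCAM- replicate 2, had 0.990. Without EpCAM+ replicate 1 and EpCAM- replicate 3 the matrix protease (adjusted p = 0.0198) and pericyte (adjusted p = 0.0291) lists passed.

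With a replicate block, 7090 genes passed (3365 higher, 3725 lower) and 21 lists, and among the lists the block changed the call of the receptor tyrosine kinases (adjusted p = 0.0509). Deviations from the group means correlated at 0.41, 0.04 and 0.16 between libraries numbered 1, 2 and 3, and not every sample correlated best with its own number, as EpCAM+ replicate 2 and EpCAM- replicate 3 had 0.23. The planned edgeR and DESeq2 alternatives were not run because whole reads were not recovered, and what depth limits is unknown.

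The 6 libraries make 10 splits into 3 and 3, so the share of splits with a result as large is never under 0.1. The real split gave 6850 changed, 3197 higher and 3653 lower genes, and the highest of the other splits gave 1 in each case, so that 1 split, the real one, reached each count. For lists the real split gave 22 and the highest other 23, so that 2 splits reached 22. The other splits called between 10 and 23 lists. Each of these splits mixes libraries of both groups on either side, so the group difference widens the spread within its sides. Few gene calls were therefore bound to follow, and neither the gene nor the list counts of these splits measure chance.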

Other observations

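All gene families, genes and tests in this part were chosen after seeing the data. Genes grouped by the stem of their symbol gave 228 families with at least 8 tested members, of which 11 passed camera. With an estimated correlation none of those named here passed (adjusted p = 0.969 for each). Zinc finger genes (Zfp) were low in EpCAM- cells, with 31 rising and 128 falling of 353 and a median of -0.36 (camera adjusted p = 0.0170). That call was lost after quantile normalisation (median -0.15, adjusted p = 0.195) and without EpCAM+ replicate 1 (adjusted p = 0.0573). Histone genes (Hist) had 10 rising and 0 falling of 23 and a median of 0.74 (adjusted p = 0.0298), with the call lost without EpCAM+ replicate 1 (0.0552), EpCAM- replicate 2 (0.0556) or EpCAM- replicate 3 (0.0591). Of 8 cullins (Cul), scaffolds of ubiquitin ligases, 7 rose (median 0.57, adjusted p = 0.0298), and the call was lost after quantile normalisation (0.0731) and without EpCAM- replicate 3 (0.0558).

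Among single genes, Nrn1 rose by 5.29 ± 0.29 (SE, limma adjusted p = 1.99e-05), the neurofilament gene Nefm by 5.22 ± 0.31 (SE), Crmp1 by 5.21 ± 0.33 (SE) and the microtubule-associated Map1a by 5.28 ± 0.41 (SE). The RNA-binding protein gene Igf2bp1 rose by 3.69 ± 0.31 (SE) and the imprinted noncoding RNA Meg3 by 3.30 ± 0.35 (SE), whereas the imprinted H19 (2.51, adjusted p = 0.110) and Igf2 (2.31, adjusted p = 0.106) did not pass.

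Matrix and fibroblast genes differed between libraries of 1 group. Of the 11 fibroblast markers that rose, 9 had both their lowest EpCAM- value in replicate 3 and their highest EpCAM+ value in replicate 1, a count taken after those libraries were seen to stand apart, which decides no source. Of the 18 listed markers 10 are also in another list, among them collagens and matrix glycoproteins, so those lists are not separate from the markers. In EpCAM- replicate 3 the median drop of these markers against the other EpCAM- libraries was 1.92 log2 units, with Col3a1 at 15.24, 16.60 and 14.36 in EpCAM- replicates 1, 2 and 3. The drop was 0.088 (SD 0.16) for the EMT factors that rose and 0.013 (SD 0.49) for all 3197 higher genes, and the shift of EpCAM+ replicate 1 against the other EpCAM+ libraries was -0.021 (SD 0.83) and 0.077 (SD 0.44) against 2.39 for fibroblast markers. The medians of all 3197 higher genes decide no source, as the values were normalised and the test favours genes with a small spread within groups. Drops of single genes among them ran from -2.19 to 3.73. The EMT factors that rose, whose largest drop was 0.24, all lay below the median drop of 1.92 of the fibroblast markers. They too were kept by the test that favours a small spread within groups, and Twist2 is in both lists. Their medians therefore decide no source either. The largest shift of an EMT factor, 1.99, was that of Prrx1, so a part of fibroblast RNA in the Prrx1 level of EpCAM+ replicate 1 stays open. Mesenchymal genes that rose (drop 0.19, SD 0.40), collagens (0.69) and matrix glycoproteins (0.98) lay between. For these and the fibroblast markers, RNA from fibroblasts, cells that the YFP gate would remove, and a difference in the matrix programme of the tumour cells both stay open.

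Acinar and islet genes were high in EpCAM+ libraries. Of the 22 acinar genes that fell, 19 were lowest in the same EpCAM+ library, replicate 2, which any acinar programme in common would also give and which decides no source. Prss2 stood at 13.24, 12.26 and 13.34 in EpCAM+ replicates 1, 2 and 3. Islet genes had a median difference of 1.91 (SD 1.60) log2 units between EpCAM+ replicates 1 and 3 and acinar genes of -0.14 (SD 0.59). This argues against 1 source that holds both in a fixed ratio. A shared source whose ratio of islet to acinar RNA varies between libraries stays open. None of the 25 acinar or 18 islet genes is in another list. Because Pdx1-Cre also marks normal pancreas, the YFP gate would not remove normal acinar or islet cells. RNA from such cells and expression by the tumour cells both stay open.

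Macrophage and MHC class II genes were high in EpCAM+ libraries, with 22 of the 24 genes that fell ordered replicate 1, 3, 2 from highest to lowest among them. That order was read from these genes, so the count decides no source, and none of the 20 macrophage or 7 class II genes is in another list. The median shift of EpCAM+ replicate 1 against replicates 2 and 3 was 1.52 for these genes and 0.032 for all tested genes. As the values were normalised between libraries, a median near 0 over all genes was set by that step and is no test. It shows only that no scaling of the whole library by as much as 1.52 remained in the deposited values. The median shift of the same library was 2.39 (SD 1.35) for fibroblast, 1.95 (SD 1.16) for islet and 0.37 (SD 0.60) for acinar genes. A lower share of tumour cells would raise all markers of other cells alike, but not acinar genes made by the tumour cells themselves, so it stays open. Lyz2 stood at 11.46, 8.89 and 9.93 and Cd74 at 11.38, 9.68 and 10.87 in EpCAM+ replicates 1, 2 and 3. Macrophage RNA, from cells that the YFP gate would remove, and class II expression by the tumour cells both stay open.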
